A study of Homo sapiens with 6 samples.

How the data were processed

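RNA was measured in 6 libraries of DLD-1 cells carrying EYFP-CENP-A, 3 untreated and 3 treated with doxycycline, each a biological replicate per the design text. Total RNA was depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols. Groups came from the treatment label, and replicates were numbered in the order of the samples, so a number names a library and pairs none. Doxycycline was given to cells with the transgene, and cells without it are not analysed here, so the drug and the induced protein cannot be separated.

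Trimmomatic, TopHat2 2.1.0, HTSeq 0.6.1, edgeR and the genome build hg19 are named in the submitters' processing notes, without their settings. The values per library were deposited as CPM, read counts scaled by the total of that library, per the file headers and the values. The 13250 listed genes hold between 99.75% and 99.82% of each library, so genes left out of the table held little of it; the rule that left them out is not given in the sources used here. Log2 fold changes and mean log2 CPM were computed by the authors and deposited per gene. A likelihood ratio score, a p-value, an adjusted p and marks for higher and lower genes were also deposited by the authors per gene, per the file headers. These marks cover 8 of the 22 genes with an adjusted p under 0.05. All 22 are described here as called in the authors' deposited table, by that threshold and not by the marks.

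Values within a library are whole multiples of 1 step, within a tolerance of 0.01 reads for 100% of values, and the step gives the library totals, 39128254 to 111343864 reads. The smallest listed values correspond to 2 to 7 reads, so that 1 read was never seen alone, and no count model was run on values rebuilt this way. The planned tests were quasi-likelihood tests on counts. The table held CPM, so the test set out for that case was used.

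Differences were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1) without further scaling, with a variance trend and Benjamini-Hochberg adjustment over 13250 genes, at an adjusted p under 0.05. All tests were two-sided. A fold change on the log2(CPM + 1) scale understates the change of low genes. No filter was added to that of the deposited table. The median SE of a log2 fold change was 0.17. Each library was counted as its own replicate, as the design text calls them. Pairs of libraries differed by a chi-square per gene of at least 49.2, computed on reads rebuilt from the step. None is thus a repeat within sampling noise, which does not test whether their cultures were separate.

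Gene lists were tested with camera on the same values, with a preset correlation between genes of 0.01, for lists of at least 5 measured members, and again with estimated correlations and with fry, which does not compare a list with other genes. The 34 lists covered the centromere, CENP-A deposition, outer kinetochore, spindle checkpoint, passenger complex, cohesin and condensin, G1/S and G2/M genes, p53 targets, DNA damage, replication-dependent and replacement histones, interferon, NF-kB, immediate early genes, the integrated stress, unfolded protein and heat shock responses, mitochondrial messenger RNAs, mitochondrial ribosomes, nuclear respiratory chain genes, ribosomal proteins, glycolysis and hypoxia, sterol synthesis, epithelial and mesenchymal genes, WNT and crypt stem cells, colonocytes, apoptosis, autophagy, fibroblast, immune and endothelial markers, and abundant noncoding RNAs. Of 983 entries 880 matched a gene of the table, 866 by symbol, 11 through the identifier of a current symbol and 3 through an older symbol. CENPA is in no list. Chromosomes 1 to 22 and X were tested as sets in the same way.

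The rule for named genes, the lists, the tests and most alternatives were fixed before the data were examined. The rule took CENPA first, then up to 10 genes per direction past the threshold whose groups did not overlap, or the 5 with the smallest p in a direction where none passed, then up to 3 members per list past the threshold, or the member with the smallest p by value. The genes called in the authors' deposited table, LGR5 and the genes of the closing observations were named after their values were seen, and 1 of the genes called there is not reported here.

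The procedure was tested on simulated data with 200 of the 13250 genes changed, in 5 draws made from the mean of each gene over all libraries plus simulated residuals. With independent residuals it recovered 94.2% of genes changed by a log2 of 1 and 100% of those changed by 2, with 6.27% of calls wrong. With the first residual component of the real libraries added, it recovered 73.6% and 98.8%, with 0% of calls wrong. With that component as a covariate it recovered 98.8% and 100%, with 4.79% of calls wrong. The covariate removes the very component that was added, so this gain was set by the simulation. The changed genes were not drawn from those of low level. With 200 changed genes the adjusted threshold is reached at a larger p than with few. These shares of recovered genes therefore need not hold where few genes change. With independent residuals, a list shifted by a log2 of 0.5 was recovered in 5 of 5 draws, with 3 of 145 other list tests called. These draws do not cover lists whose genes vary together, so this share of calls need not hold for the real lists. GENCODE v29 on GRCh38 served only for overlaps, pseudogene names, lengths and GC content of genes matched by identifier, and coordinates are those of the deposited table. Alternatives covered scaling, pseudocounts, filters, moderation, a covariate and left-out libraries.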

Results

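RNA levels were measured in DLD-1 cells, an established human colorectal cancer line, transduced with EYFP-CENP-A, a fusion of a yellow fluorescent protein with the histone H3 variant that marks centromeres. Cells were left untreated or received a 30 min pulse of doxycycline at 0.1 µg/mL, PBS washes and 20 to 30 h of washout, and total RNA depleted of ribosomal RNA was sequenced from 3 biological replicates of each condition. The table held 13250 genes, of which 11782 were protein-coding, 426 lincRNAs and 401 antisense genes. The step between values put library totals at 57574339, 39128254 and 101288296 reads for untreated replicates 1, 2 and 3, and at 111343864, 73244454 and 46069970 reads for doxycycline replicates 1, 2 and 3. Genes of the mitochondrial genome took 18.3%, 8.26% and 18.7% of the reads of the untreated libraries and 14.7%, 12.0% and 19.0% of those of the doxycycline libraries. The mitochondrial large ribosomal RNA gene MT-RNR2 was the most abundant gene in all 6 libraries. Pearson correlations of log2(CPM + 1) across genes, which are not independent replicates, were 0.980 to 0.993 within groups and 0.977 to 0.994 between groups.

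The first principal component held 52.5% of the variance and placed untreated replicate 2 at 28.8 and doxycycline replicate 2 at 26.3, with untreated replicates 1 and 3 at -10.6 and -18.9 and doxycycline replicates 1 and 3 at -8.67 and -17.0. The second component held 21.5% of the variance, with the untreated libraries at -12.9, -16.6 and -4.12 and the doxycycline libraries at 2.86, 18.8 and 12.0.

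**Figure D1:**
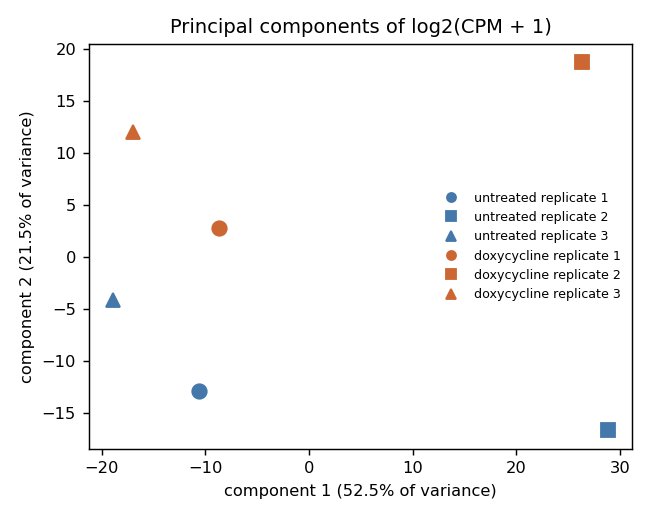
Scores of the 6 libraries on the first component (52.5% of variance, x axis) and the second component (21.5%, y axis) of log2(CPM + 1), with colour for the group and marker shape for the replicate. Untreated replicate 2 and doxycycline replicate 2 lie together on the right, and the groups lie on opposite sides of 0 on the second component.

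The series title concerns CENP-A overexpression, and the level of CENPA was the first comparison. CENPA (ENSG00000115163; hg19 chromosome 2, 26987157 to 27023935, plus strand, protein-coding) rose from 23.4 ± 2.64 CPM (SD, n = 3) in untreated cells to 620 ± 163 CPM (SD, n = 3) in doxycycline-treated cells. The untreated libraries held 20.4, 24.4 and 25.3 CPM and the doxycycline libraries 624, 781 and 455 CPM. The ratio of the means was 26.5, and ratios of single libraries ran from 18.0 to 38.3. Among the 13250 genes CENPA moved from rank 7400, 6622 and 6757 in the untreated libraries to rank 108, 85 and 186 in the doxycycline libraries. The transgene carries the CENPA coding sequence, so its reads can be counted for this gene. The values do not separate them from reads of the native gene, and their share was not tested.

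The log2 fold change of CENPA was 4.64 ± 0.19 (SE, limma, 95% confidence interval 4.22 to 5.06), with an adjusted p of 2.89e-06. The authors' deposited table gave it a log2 fold change of 4.72 and an adjusted p of 3.77e-66. An exact two-sided permutation test of the means gave p = 0.10, the smallest that 3 against 3 libraries allow.

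**Figure D2:**
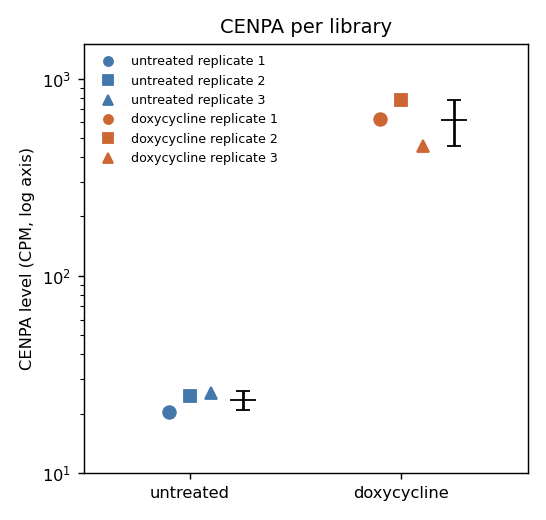
CENPA level in CPM on a log axis for the 3 untreated and 3 doxycycline libraries, with 1 marker shape per replicate, horizontal bars for the group means and error bars for the SD. The untreated libraries lie between 20.4 and 25.3 CPM and the doxycycline libraries between 455 and 781 CPM.

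The next comparison asked which other genes differed between doxycycline-treated and untreated cells. CENPA was the 1 gene of 13250 past the threshold in the limma test of all 6 libraries, and 0 genes fell. At an unadjusted p under 0.05 there were 318 genes with higher and 266 with lower values, 584 in all, against 662.5 from chance, and the next smallest adjusted p was 0.503. Variation shared by libraries across the groups stays in the residuals of this test and can lower that count. With 1 library left out it ran from 264 to 723. In fits chosen after seeing the data it was 1481 with array weights and 1665 with the first residual component as a covariate, which lowers the residuals by construction. In 600 genes all 3 doxycycline libraries lay above all 3 untreated libraries and in 638 they lay below, together 9.34% of genes, where chance gives 10%. The authors' deposited table, made with edgeR, has 22 genes with an adjusted p under 0.05, of which 6 are higher and 16 lower after doxycycline. It has 537 genes at an unadjusted p under 0.05.

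Among the genes higher in the authors' deposited table besides CENPA, the imprinted noncoding RNA H19 had 34.7 ± 5.50 CPM in untreated and 75.7 ± 18.5 CPM in doxycycline-treated cells (SD, n = 3 each). HSPA5, the endoplasmic reticulum chaperone BiP, had 123 ± 32.4 and 229 ± 44.0 CPM. SNRPA1, a protein of the U2 spliceosomal particle, had 17.3 ± 8.54 and 36.3 ± 4.32 CPM, and untreated replicate 3 with 27.1 CPM lay nearer to the doxycycline libraries than to the 12.2 and 12.4 CPM of the other untreated libraries. The small nucleolar RNA SNORA53 had 1.17 ± 0.629 and 6.08 ± 3.99 CPM. Their adjusted p values were 3.07e-05, 0.0321, 0.0466 and 0.00583 in the authors' deposited table, in the order given here.

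Among the 16 genes lower in the authors' deposited table, TNFRSF19, a TNF receptor family member expressed in intestinal crypt stem cells, had 42.4 ± 7.18 CPM in untreated and 17.6 ± 4.71 CPM in doxycycline-treated cells. GNE, the enzyme that starts sialic acid synthesis, had 68.5 ± 7.38 and 37.9 ± 3.36 CPM, and ANKRD22 had 21.9 ± 4.35 and 8.94 ± 3.00 CPM. NEDD9, a focal adhesion scaffold protein, had 38.2 ± 9.09 and 19.7 ± 1.12 CPM. The adhesion receptors LPHN2 and GPR115 had 28.7 ± 2.95 and 13.4 ± 0.492 CPM in untreated cells and 15.1 ± 3.12 and 6.76 ± 1.19 CPM after doxycycline. The transcription factor HOXA11 had 41.7 ± 4.52 and 23.5 ± 4.60 CPM, the chromatin regulator ARID5B 115 ± 24.1 and 66.2 ± 11.4 CPM, and TMEM52B 137 ± 3.78 and 87.6 ± 6.99 CPM. IL22RA1, a subunit of the interleukin 22 receptor, had 22.1 ± 2.53 and 11.8 ± 2.99 CPM, and the retroviral restriction factor TRIM5 had 54.2 ± 2.64 and 34.6 ± 2.66 CPM. The other lower genes were SH3TC2, DAPK3, NAV3, C1orf116 and FAM63A, with doxycycline means at 49.5% to 64.4% of the untreated means.

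In all 22 genes the groups did not overlap and the limma fold change had the same sign. They were picked from these same libraries, so this is no separate support. Apart from CENPA none of them passed in the limma test of all 6 libraries without covariates, where their adjusted p ran from 0.503 to 0.880. In fits chosen after seeing the data, limma called all 22, CENPA included, with the first residual component as a covariate, 10 with array weights and 4 without both replicate 2 libraries. The 5 genes with lower values and the smallest p in limma were GNE (log2 fold change -0.84 ± 0.13, SE), TNFRSF19 (-1.24 ± 0.20), TMEM52B (-0.64 ± 0.12), GPR115 (-0.91 ± 0.17) and NEDD9 (-0.90 ± 0.17). In GENCODE v29, 9 of the 22 genes overlap another gene on the same strand and 10 overlap one on the opposite strand. Such overlaps are common, since 70.2% of 10577 genes with a mean of at least 4 CPM overlap another gene on either strand. Whether reads were counted by strand is not given in the sources used here. Without untreated replicate 3, limma gave 27 higher genes and 1 lower gene, GNE, and 5 of these 28 were among the 22 of the authors' deposited table.

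**Figure D3:**
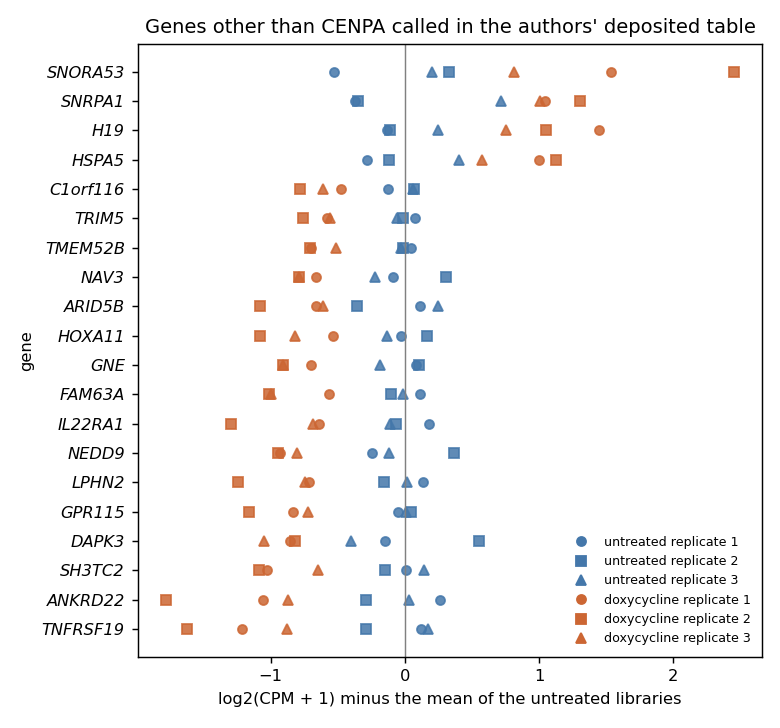
Levels of 20 genes other than CENPA with an adjusted p under 0.05 in the authors' deposited table, as log2(CPM + 1) minus the mean of the untreated libraries (x axis), 1 row per gene, with colour for the group and marker shape for the replicate. In every row the 3 doxycycline libraries lie on 1 side of the 3 untreated libraries.

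Genes of chromosome segregation were examined next, since CENP-A sets the place of the kinetochore. Of 54 genes expressed in the G2 and M phases, 51 had positive log2 fold changes, with a median of 0.13. The list passed camera upward with the preset correlation (adjusted p = 1.35e-07) but not with the correlation estimated from the data (adjusted p = 0.916 with an estimated correlation). TACC3, a spindle protein and the member with the smallest p, had 32.8 ± 12.0 CPM in untreated and 59.1 ± 3.42 CPM in doxycycline-treated cells (SD, n = 3 each), and untreated replicate 3 with 46.6 CPM lay above the 27.1 and 24.8 CPM of the other untreated libraries. The 23 cohesin and condensin genes, 21 of them with positive values and a median of 0.11, passed upward (adjusted p = 0.00738), as did the 15 genes of the chromosomal passenger complex and its partners (adjusted p = 0.0424, median 0.10). Both calls were lost with the estimated value (adjusted p = 0.916 with an estimated correlation for each list). The condensin subunit NCAPD2 had 218 ± 29.2 and 272 ± 18.6 CPM, and the centromeric cohesin protector SGOL2 had 63.8 ± 7.98 and 91.2 ± 23.4 CPM. Against the untreated mean, median levels of the G2 and M list were -0.03, 0.11 and -0.10 in untreated replicates 1, 2 and 3 and 0.05, 0.33 and 0.09 in doxycycline replicates 1, 2 and 3, so that untreated replicate 2 lay above 2 of the doxycycline libraries.

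Centromere proteins themselves did not pass as a list. The 17 genes of the constitutive centromere network had a median log2 fold change of 0.07 (camera adjusted p = 0.567), and CENPB, which binds centromeric satellite DNA, had 72.1 ± 3.57 and 59.7 ± 7.21 CPM. The 22 genes of CENP-A deposition, chaperones included, had a median of 0.03 (adjusted p = 0.424), and the remodelling factor RSF1 had 48.2 ± 9.32 and 58.0 ± 2.33 CPM. The 21 outer kinetochore genes had a median of 0.07 (adjusted p = 0.136) and the 10 spindle checkpoint genes one of 0.12 (adjusted p = 0.191), with SPC25 at 15.6 ± 1.55 and 19.8 ± 2.79 CPM and BUB1 at 202 ± 35.3 and 240 ± 51.4 CPM. The 38 genes of G1 and S phase had a median of 0.00 (adjusted p = 0.567), and the replicative helicase subunit MCM6 had 103 ± 11.3 and 134 ± 15.7 CPM.

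Histone and interferon genes passed camera downward with the preset correlation. Of 48 replication-dependent histone genes, 41 had negative log2 fold changes (median -0.09, camera adjusted p = 0.00248), and of 23 interferon-stimulated genes 18 did (median -0.19, adjusted p = 0.00738). Neither list passed with the estimated value (adjusted p = 0.916 with an estimated correlation for each list). The linker histone gene HIST1H1D had 322 ± 33.8 and 240 ± 53.8 CPM, and USP18, which restrains interferon signalling, had 13.7 ± 3.14 and 9.82 ± 0.573 CPM. The histone list had a median of -0.49 against the untreated mean in doxycycline replicate 2 and of 0.04 and 0.07 in doxycycline replicates 1 and 3, and the interferon list had -0.30 in doxycycline replicate 2, -0.01 and -0.03 in doxycycline replicates 1 and 3, and 0.06, -0.13 and 0.06 in untreated replicates 1, 2 and 3. The 9 replacement histone genes had a median of 0.06 (adjusted p = 0.424), and H3F3A, which has pseudogene copies that can share its reads, had 34.0 ± 4.61 and 43.5 ± 4.75 CPM.

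Heat shock genes and mitochondrial messenger RNAs also passed upward with the preset correlation. Of 18 heat shock genes 15 had positive values (median 0.17, camera adjusted p = 0.0289), and of 13 protein-coding genes of the mitochondrial genome 12 did (median 0.44, adjusted p = 0.0331). Both calls were lost with the estimated value (adjusted p = 0.916 with an estimated correlation for each list). The chaperone HSP90AA1 had 810 ± 152 and 1487 ± 634 CPM, with 2216 CPM in doxycycline replicate 2. MT-ATP8, a subunit of ATP synthase, had 43.9 ± 37.1 and 59.2 ± 16.8 CPM, with 10.6 CPM in untreated replicate 2. The medians of the mitochondrial list were 0.26, -1.17 and 0.90 in untreated replicates 1, 2 and 3 and 0.53, 0.02 and 0.87 in doxycycline replicates 1, 2 and 3, relative to the untreated mean.

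In total 7 of the 31 lists tested passed camera with the preset correlation, 5 upward and 2 downward. With estimated correlations 0 passed, and fry called 0 lists, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.939. Leaving out 1 library changed these calls. Lists passing upward numbered 12 without untreated replicate 2, 8 without doxycycline replicate 3, 3 without untreated replicate 3 and 3 without doxycycline replicate 2, and in each of the last settings 0 lists passed downward. The G2 and M list passed without any 1 library, with its largest adjusted p, 0.0390, without doxycycline replicate 2. Without untreated replicate 3 and without doxycycline replicate 2, the adjusted p was 0.113 and 0.197 for cohesin and condensin, 0.543 and 0.699 for the passenger complex, 0.0542 and 0.1705 for replication-dependent histones, 0.0710 and 0.306 for interferon-stimulated genes and 0.729 and 0.771 for heat shock genes. Without untreated replicate 1 it was 0.391 for the passenger complex and 0.608 for heat shock genes. The mitochondrial list lost its call without untreated replicate 2, doxycycline replicate 1 or doxycycline replicate 3 (adjusted p = 0.1455, 0.08635 and 0.433). Without doxycycline replicate 2 the histone list pointed upward and the heat shock list downward, and without untreated replicate 2 the mitochondrial list pointed downward.

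Single members of the lists did not pass over all genes. Over all 34 lists limma called 0 members at the adjusted threshold over all genes, 32 entries had a higher and 9 a lower value at an unadjusted p under 0.05, and 2 members, HSPA5 and TNFRSF19, were among the calls of the authors' deposited table. Adjusted over the list alone, without correction for the number of lists, 5 members passed. The p53 target PLK2, a polo-like kinase, rose from 124 ± 4.94 to 174 ± 6.59 CPM (adjusted p = 0.0383 in limma). HSPA5 rose among 20 genes of the unfolded protein response (adjusted p = 0.0226). Among 19 WNT target and crypt stem cell genes, TNFRSF19 fell (adjusted p = 0.00216) and LGR5, a receptor that marks crypt stem cells, rose from 16.4 ± 2.29 to 26.2 ± 4.05 CPM (adjusted p = 0.0271). VIL1, a protein of the microvilli of enterocytes, rose from 1.62 ± 0.544 to 3.42 ± 0.327 CPM among 10 colonocyte genes (adjusted p = 0.0414). In each of the other 30 lists the count adjusted over the list alone was 0. With 34 lists adjusted apart, some such calls can arise by chance. Over all genes the limma adjusted p was 0.853 for PLK2, 0.842 for HSPA5, 0.503 for TNFRSF19 and 0.986 for VIL1.

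The other lists did not pass camera. Among stress and damage lists, the medians were 0.05 for 26 p53 targets (adjusted p = 0.136), 0.01 for 32 DNA damage genes (0.545), 0.02 for the unfolded protein response (0.272), 0.01 for 27 targets of the integrated stress response (0.870), -0.05 for 24 apoptosis genes (0.424) and 0.01 for 27 autophagy and lysosome genes (0.870). The immediate early genes had a median of -0.04 while their mean was 0.08 and camera pointed upward (adjusted p = 0.567), and NR4A3, an orphan nuclear receptor, had 5.57 ± 1.11 and 9.75 ± 1.09 CPM. The 20 NF-kB and inflammatory genes had a median of -0.07 (adjusted p = 0.424), and BIRC3, an inhibitor of apoptosis, had 36.9 ± 4.82 and 25.0 ± 3.99 CPM. Named by the smallest p of their lists, H2AFX had 140 ± 24.4 and 174 ± 28.6 CPM, ATF5 10.8 ± 2.098 and 15.2 ± 2.11 CPM, MCL1 194 ± 16.9 and 236 ± 31.3 CPM, and GABARAPL1 80.3 ± 0.457 and 62.2 ± 2.73 CPM.

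Metabolic lists had medians of 0.03 for 75 mitochondrial ribosome genes (adjusted p = 0.567), 0.03 for 76 nuclear respiratory chain genes (0.706), 0.04 for 27 glycolysis and hypoxia genes (0.272) and 0.02 for 25 sterol synthesis genes (0.507). MRPL22 had 15.6 ± 3.42 and 20.9 ± 3.38 CPM, UQCRFS1 105 ± 4.46 and 84.6 ± 6.30 CPM, HK2 37.4 ± 2.39 and 48.5 ± 10.1 CPM, and NSDHL 19.2 ± 2.36 and 25.9 ± 3.48 CPM. The 78 ribosomal protein genes had a median of -0.02 and a mean of 0.03 (adjusted p = 0.643). Among them RPS16 had 36.7, 26.9 and 341 CPM in the untreated and 419, 285 and 414 CPM in the doxycycline libraries. Pseudogenes named after RPS16, MRPL22, UQCRFS1, HK2, BUB1, NCAPD2 and H3F3A can share their reads, so these levels are uncertain.

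Lists of cell identity gave medians of -0.03 for 22 epithelial genes (adjusted p = 0.136), -0.05 for 15 mesenchymal genes (0.840), 0.01 for the crypt stem cell genes (0.999), whose mean was -0.01, and -0.03 for the colonocyte genes (0.545), whose mean was 0.12. CLDN4, a tight junction protein, had 207 ± 33.6 and 147 ± 22.8 CPM, and CDH2, the neural cadherin, had 1.16 ± 0.388 and 0.502 ± 0.253 CPM. The 15 abundant noncoding RNAs had a median of 0.04 (adjusted p = 0.424), with SNORD17 at 47.9 ± 7.01 and 61.3 ± 5.64 CPM. Of the markers of other cell types, 1 of 11 fibroblast, 2 of 16 immune and 1 of 9 endothelial genes were in the table, too few for a list test. COL3A1 had 1.53 ± 1.41 and 0.502 ± 0.608 CPM, LYZ 1.41 ± 0.354 and 1.87 ± 0.261 CPM, and ESAM 4.63 ± 0.378 and 4.46 ± 1.35 CPM.

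**Figure D4:**
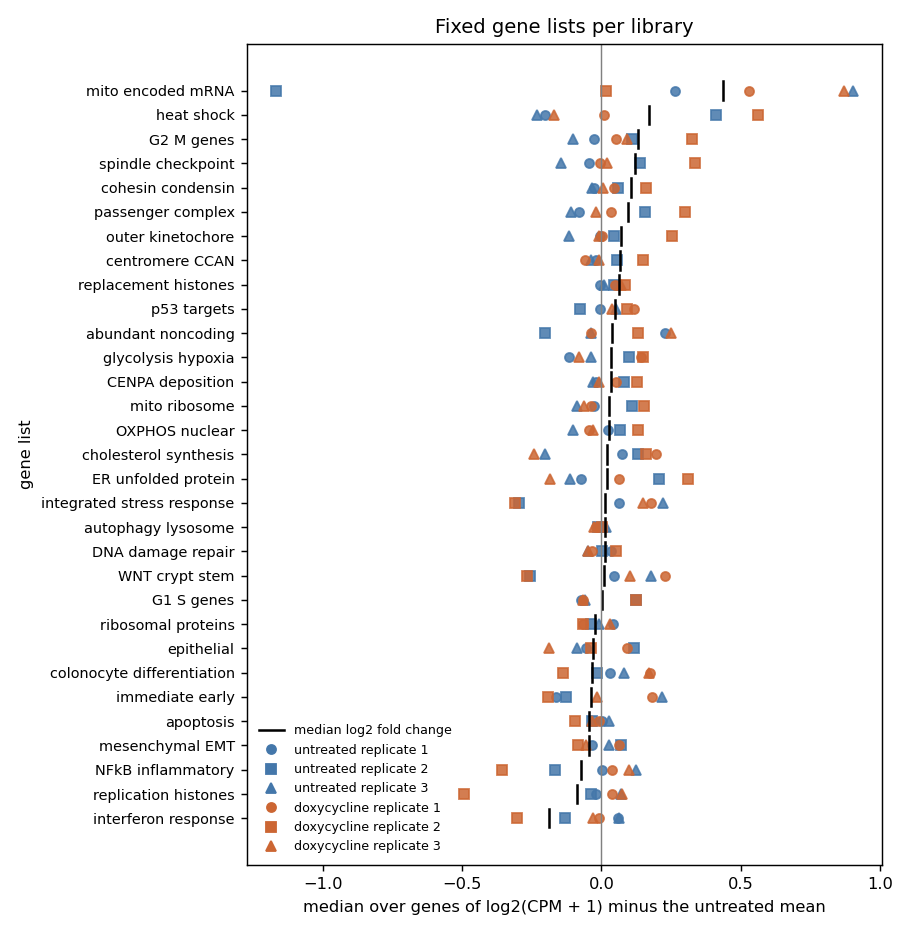
Median over the genes of each of the 31 lists tested of log2(CPM + 1) minus the mean of the untreated libraries (x axis), 1 row per list, with colour for the group and marker shape for the replicate, and a black bar for the median log2 fold change. In the mitochondrial list untreated replicate 2 lies at -1.17, and in the histone list doxycycline replicate 2 lies at -0.49.

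Because the series title also names aneuploidy, genes were grouped by chromosome to look for shifts of whole chromosomes between the groups. Median log2 fold changes of the 23 chromosomes ran from -0.03 for chromosome 19 (843 genes) to 0.04 for chromosome 13 (220 genes). A gain of 1 copy by all cells with 2 copies would give 0.58 if RNA followed copy number. No chromosome passed camera (0 of 23, smallest adjusted p 0.934), 0 had an unadjusted p under 0.05, and camera with estimated correlations and fry also called 0. Without doxycycline replicate 1, chromosomes 19 and 22 passed downward (adjusted p = 0.0315 for each). Averages over the cells of a culture do not show gains and losses that differ from cell to cell.

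**Figure D5:**
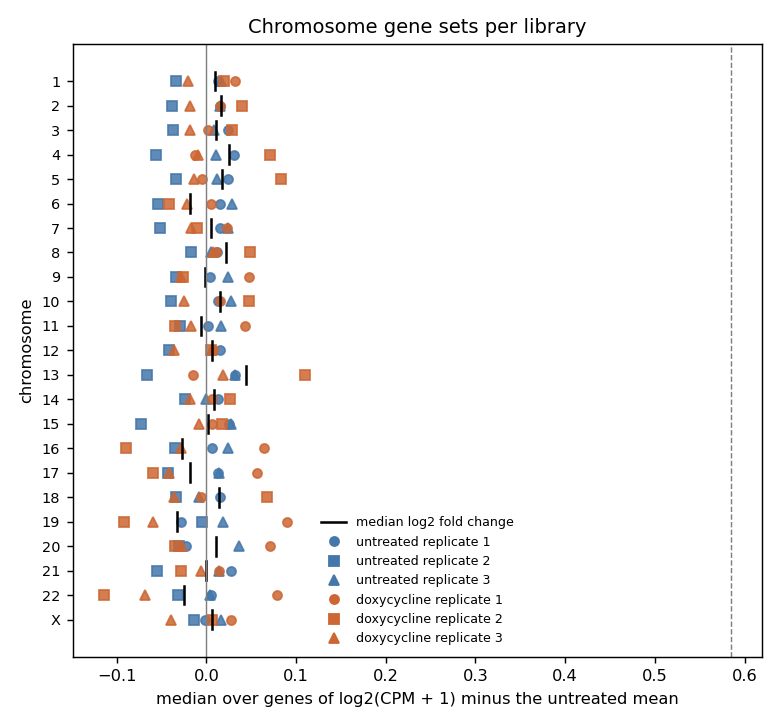
Median over the genes of each chromosome of log2(CPM + 1) minus the mean of the untreated libraries (x axis), 1 row per chromosome, with colour for the group and marker shape for the replicate, and a black bar for the median log2 fold change. All values lie close to 0 compared with the dashed line at 0.58, the shift of 1 extra copy on 2.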

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

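The settings with array weights, a residual covariate, other pseudocounts in the tests of genes, trimmed mean factors, other moderation, or a pair of libraries left out were chosen after seeing the data. So were those without mitochondrial genes for lists and chromosomes. CENPA passed under all 22 alternatives, with log2 fold changes of 4.43 to 4.85 and adjusted p of 3.77e-66 to 5.91e-04, and from 4.46 to 4.85 with 1 library left out. Genes higher and lower, CENPA among the higher, numbered 6 and 16 in the authors' deposited table, 2 and 9 with array weights, 116 and 79 with the first residual component as a covariate, 2 and 3 without both replicate 2 libraries, and 2 and 0 without untreated replicates 1 and 2, where the lone untreated library was assumed to vary like the others. With 1 library left out they ran from 1 to 27 higher and from 0 to 1 lower. Other scalings, pseudocounts, filters, moderation and a test against a log2 of 0.5 gave 1 higher, CENPA, and 0 lower. Scalings moved the median of all genes to between 5.71e-04 and 0.00328 (log2).

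Lists passing upward and downward numbered 0 and 0 with estimated correlations and with fry, 4 and 1 without both replicate 2 libraries, and 13 and 7 without untreated replicates 1 and 2, and with 1 library left out 3 to 12 and 0 to 3. Chromosomes passing downward ran from 0 to 2 with 1 library left out and upward 0 throughout. Some lists turned direction, and the cause was not tested. Without untreated replicate 2 the integrated stress response passed downward (adjusted p = 0.0493) and mitochondrial messenger RNAs pointed downward (0.146). Without doxycycline replicate 2 replication-dependent histones pointed upward (0.171) and heat shock downward (0.771), and without both replicate 2 libraries the histones pointed upward (0.175). Without untreated replicates 1 and 2, immediate early genes (0.00821), the integrated stress response (6.05e-05), mitochondrial messenger RNAs (1.24e-07) and WNT and crypt stem cell genes (0.0111) turned. With 1 library left out the adjusted p ran from 3.97e-10 to 0.1705 for these histones, 0.00696 to 0.832 for the integrated stress response, 5.33e-08 to 0.771 for heat shock and 3.82e-09 to 0.433 for mitochondrial messenger RNAs. Of the other values for single genes, lists and chromosomes, 1858 kept direction and side of the threshold or passed in neither fit, 28 lost a call and 101 gained one. Quasi-likelihood, DESeq2 and voom fits need counts and were not run, since no count model was run on reads rebuilt from the step. The gap between 1 gene in limma and 22 in the authors' deposited table was therefore not resolved. A fit without a filter is the one reported. No paired analysis was run, because the labels give no replicate numbers shared by the groups. Libraries of the same number lay near each other on the first component. If they share a source of variation, it remains in the residuals of the main test, which could then miss changes. Each library held at least 39128254 reads, and whether counting error or the spread between libraries limits a given value was not tested.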

Other observations

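The tests of sequencing depth and of the shift given by the mitochondrial share below were chosen after the results they bear on were seen. So were the covariate fit, the left-out pairs of libraries and the genes named here. Several genes differed more between libraries of a group than between the groups. ANKRD1 and CYR61, targets of the YAP coactivator, had 26.7 and 44.2 CPM in untreated replicate 2, 60.05 and 68.0 CPM in doxycycline replicate 2, and at most 15.1 and 20.1 CPM in the other 4 libraries. THBS1, a matrix glycoprotein, had 348 and 273 CPM in these replicates and at most 143 CPM elsewhere. TXNIP, a regulator of glucose uptake, had 75.0 and 64.5 CPM there and at least 199 CPM elsewhere, S100P, a calcium-binding protein, 60.1 and 65.6 CPM against at least 174.5 CPM, and the trefoil peptide TFF1 1.48 and 1.04 CPM against at least 4.41 CPM. Median levels of the heat shock list were 0.41 and 0.56 above the untreated mean in these replicates, and at most 0.01 above it in the others.

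Untreated replicate 2 and doxycycline replicate 2 were set apart by 196 of 10758 genes with a mean of at least 4 CPM, 29 higher and 167 lower by a gap above 0.6 in log2(CPM + 1), the most of the 15 pairs of libraries. The share of mitochondrial reads was lower in these libraries, 8.26% and 12.0%. Alone it would raise other genes in them by a log2 of 0.044 to 0.18 against the other 4 libraries. This argues against such scaling as the cause of the lower genes, apart from 1 mitochondrial gene among them. For the higher genes the size of the shift is no test, since a gap above 0.6 was the condition of their choice. In a test set out before its result was seen, mitochondrial genes were left out and the rest rescaled. Then 289 genes were lower and 12 higher in the pair, against 167 and 29. The pair still stood apart, while the scaling may account for part of the higher genes. Transcript length did not follow the loadings of genes on the first component beyond a Spearman rho of -0.0958 (across genes, which are not independent), and sequencing depth was argued against, because doxycycline replicate 2 had rank 4 from the lowest of the 6 read totals. A culture or library batch shared by these libraries may account for the pair and stays open, as does GC content, which had a rho of -0.214 with the loadings. No biological explanation was tested, since the labels name no difference besides the treatment.

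A further pattern lay within the untreated group, where 37 genes were lower in replicates 1 and 2 than in the other 4 libraries by a gap above 0.6 and 0 were higher, while pairs of libraries other than these and the replicate 2 pair gave at most 3 lower genes. HNRNPH3, a splicing factor, had 18.7 and 12.1 CPM in them and at least 77.0 CPM elsewhere, the DNA repair enzyme APEX1 64.3 and 60.3 against at least 228 CPM, and the adaptor MYD88 8.35 and 4.83 against at least 29.2 CPM. Overlap with another annotated gene was present in 59.5% of the 37 (exact 95% interval 42.1 to 75.2) and in 70.2% of the other genes, and a pseudogene named after the gene in 21.6% (9.83 to 38.2) and 12.7%, which argues against either as the cause of the whole pattern. Sequencing depth was argued against too, because the pair of shallowest libraries, untreated replicate 2 and doxycycline replicate 3, gave 0 such genes. A difference in the preparation of these libraries may remain, and of the 27 genes higher without untreated replicate 3, 23 belonged to the 37.

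With the first residual component as a covariate, 116 genes were higher and 79 lower, all 22 of the authors' deposited table among them. The 6 libraries can be split in 10 ways, too few for a share under 0.05. Of these splits 3, the real one included, gave at least as many as the real 195. Splits with both replicate 2 libraries on the same side gave 861, 545, 149 and 21 genes, which points to a structure of the libraries beyond the groups. Splits that part them, other than the real one, gave 0, 0, 1, 0 and 0. The replicate 2 pair was found from the data, so this comparison does not decide whether the 195 follow the treatment. Of the 116 higher genes 80.2% (exact 95% interval 71.7 to 87.0) were lower in untreated replicates 1 and 2 than in all other libraries, and of the 79 lower genes 31.6% were higher in these libraries than in all others. Of the 37 genes above, 27 were among the 116. Genes called higher after doxycycline already tend to lie low in the untreated libraries, so the share of 80.2% alone does not decide whether they follow the pattern of untreated replicates 1 and 2, and that pattern and an effect of the treatment both stay open.

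For the other results the 10 splits were also too few for a share under 0.05, and the counts of splits as large include the real one. The real split gave 1 gene in limma and the highest other 0, with 1 split as large. It gave 7 lists with the preset correlation and the highest other 20, with 8 splits as large. It gave 0 chromosomes and the highest other 7. With a real count of 0 all 10 are as large whatever the data, so that count decides nothing.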
